A study of Mus musculus with 6 samples.

How the data were processed

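The hippocampal transcriptome was measured in 6 mouse libraries, 3 Control and 3 TAF15 OE, made with a TruSeq RNA kit from Trizol-extracted RNA and sequenced on a NovaSeq 6000, as the labels state. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, CASAVA, Bowtie2 2.2.3, HISAT2 2.1.0 and TopHat2 were used, with genome build GRCm38; the role of each, the read counter, the annotation release, the strandedness and any filter were not given in the sources used here. The deposited count table holds raw counts per Ensembl gene for each library, as whole numbers. A deposited table of FPKM values (fragments scaled by gene length and library total) lists the genes with a count above 0; in 8926 genes with over 200 counts in every library, each value equalled the count over a gene length and the library total within a relative deviation of 3.89e-09. The authors' comparison table repeats the raw counts, which equalled the count table in 100% of cells. It adds a normalised signal made by the authors, the mean over libraries of counts divided by size factors, which median-of-ratios size factors gave within a relative deviation of 2.85e-09. It also gives the authors' fold change as a ratio and as a log2 value, TAF15 OE over Control, and the authors' p-value and adjusted p-value, whose test is not named. The adjusted p-value is NA for 13762 genes in the authors' table.

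Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and each gene was tested with a quasi-likelihood F-test (glmQLFit with robust estimation, group as the only term), with p adjusted by Benjamini-Hochberg over the 16758 tested genes and called at an adjusted p below 0.05. The scaling factors lay between 0.964 and 1.03, the biological coefficient of variation was 13.1%, and the 10 most abundant genes held between 5.20% and 6.51% of the counts of a library. Total counts ran from 14965464 to 16067000 per library. Standard errors are of the log2 fold change and come from the F statistic of each gene. Symbols, types and positions came from the authors' table; 16736 of the tested genes were found by identifier in GENCODE M21, 15141 of them at the same position. Taf15 and Npas4 overlap no other annotated gene there.

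In all, 51 gene lists (cell type markers, pathways and signs of RNA quality) were compared with the other genes by camera in limma 3.58.1 on log2 CPM (counts relative to the scaled library total, prior count 2), with a preset correlation between genes of 0.01, for the 49 lists with at least 5 tested members. The p was adjusted over the lists, and called at an adjusted p below 0.05. Each list was also tested with an estimated correlation and by fry, and its members were adjusted over the list alone. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Under that rule Taf15, Ewsr1 and Npas4 were named whatever their result. Then came the 12 called genes with the largest change in each direction, with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes and pseudogenes. Last came up to 4 members with the smallest p of each list that passed and of the immediate early, late activity-response, glutamate receptor, CA1, reactive astrocyte and microglia lists. A direction with fewer than 5 calls would have been filled up to 5 by p, which was not needed. A further 6 genes are not reported here.

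The alternatives were the size factors of DESeq2 1.42.0, total counts alone, no filter, a mean of at least 1 CPM, DESeq2, limma-voom, a limit of 1 on the absolute log2 fold change with adjusted or unadjusted p, and limma-trend on log2 FPKM with a pseudocount of 1 or 0.1, with genes of a mean FPKM of at least 0.5 or no filter. Further ones were the replicate number as a block, leaving out each library in turn, and the other tests of lists. Leaving out Control 1 and TAF15 OE 1 together, and scaling on the 35 presynaptic release machinery genes, were chosen after the data were seen. The fits were tested on simulated counts with 16454 genes and seeded changes. edgeR recovered 40.3% of genes with an absolute log2 fold change of 0.5, 64.2% at 1 and 98.5% at 2, with 6 false calls of 153, and each list test recovered the seeded list with 0 false lists. The simulated genes were drawn independently of each other and the simulated lists at random. The simulation therefore cannot show how often the list tests call lists of correlated genes falsely. No 2 libraries were duplicates: the smallest chi-square per degree of freedom between libraries was 5.18. The labels give no batch, and no library was left out of the main results. Figures were drawn with matplotlib 3.10.9.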

Results

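RNA was sequenced from the hippocampus of 6 male C57BL/6J mice, with 1 mouse per library. In 3 mice an adeno-associated virus carrying TAF15, whose label names the CaMKIIα promoter of excitatory neurons, had been injected into the CA1 field of both hippocampi (TAF15 OE). The other 3 mice had been given a control virus (Control). Injection was at 8 weeks of age, and the labels give 31 days for all 6. TAF15 is an RNA-binding protein related to EWSR1, and also associates with the transcription factor TFIID. The series title names memory and the transcription of Npas4, a neuronal activity-induced transcription factor, so the comparison asks which hippocampal transcripts differed between mice with raised TAF15 and their controls. The libraries held 15297578, 15112704 and 15210192 counts in Control 1, 2 and 3 and 15629757, 14965464 and 16067000 in TAF15 OE 1, 2 and 3. Of 52550 genes in the count table, 30821 had a count in at least 1 library and 16758 were tested. The first principal component carried 46.3% of the variance and separated the groups, and the second carried 21.7% and set Control 1 and TAF15 OE 1 apart from the other 4 libraries. In Control 1 the choroid plexus transcript Ttr stood at 89.3 CPM (a normalised read count, relative to the scaled total of its library), against 4273 and 3839 in Control 2 and 3, and in TAF15 OE 1 at 1356, against 4140 and 4477 in TAF15 OE 2 and 3. The invariant chain gene Cd74 stood at 562 CPM in TAF15 OE 1, against 59.2 and 118 in TAF15 OE 2 and 3.

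**Figure D1:**
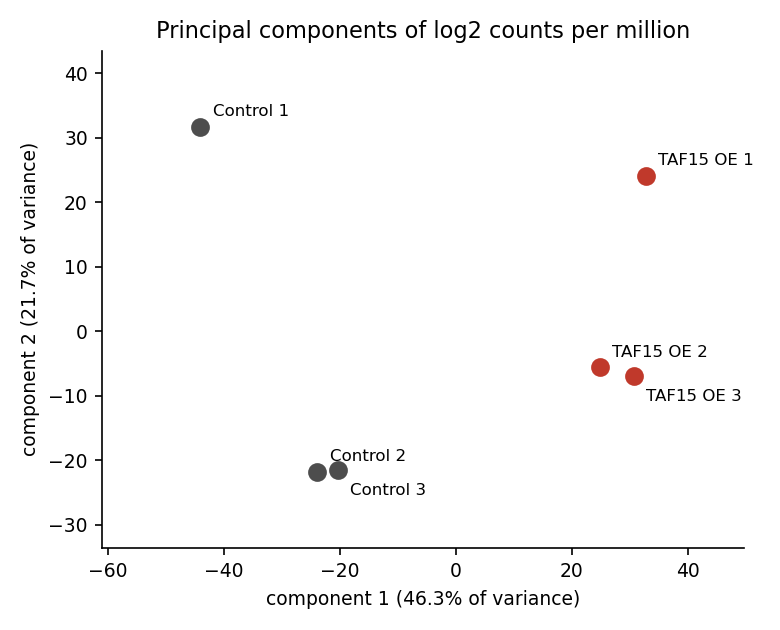
Each point is 1 library, placed by its first (46.3% of the variance) and second (21.7%) principal component of log2 CPM, grey for Control and red for TAF15 OE. The groups part along the first component, and Control 1 and TAF15 OE 1 lie above the other 4 libraries on the second.

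Taf15 was 4.27-fold higher in TAF15 OE, and Npas4 was 3.17-fold lower. Taf15 (ENSMUSG00000020680, chromosome 11, 83473086 to 83506743, plus strand, GRCm38) had 908, 958 and 795 counts in Control 1, 2 and 3 and 3897, 3661 and 4477 in TAF15 OE 1, 2 and 3. This was 59.4 ± 5.64 CPM in Control and 254 ± 16.1 in TAF15 OE (mean ± SD, n = 3 mice in each group, as for all levels that follow), a log2 fold change of 2.1 (SE 0.086, adjusted p = 4.97e-07). The sequence of the vector's insert was not given in the sources used here, so these counts do not part vector transcript from the mouse's own. The related gene Ewsr1 did not pass the test, with a log2 fold change of 0.025 (SE 0.070, adjusted p = 0.858). Its sign turned without Control 1 (-0.018) and without TAF15 OE 3 (-0.019).

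Npas4 (ENSMUSG00000045903, chromosome 19, 4984355 to 4989971, minus strand) had 279, 260 and 293 counts in Control 1, 2 and 3 and 77, 51 and 152 in TAF15 OE 1, 2 and 3. Its level was 18.6 ± 1.19 CPM in Control and 5.83 ± 3.04 in TAF15 OE, and it fell by 1.66 on the log2 scale (SE 0.33, adjusted p = 0.0177), with all 3 TAF15 OE libraries below all 3 Control libraries. The fold change was negative with each library left out, between -2.17 and -1.41, but the call was lost without Control 1 (adjusted p = 0.0586), Control 2 (0.0559), Control 3 (0.0536) or TAF15 OE 1 (0.0760). It was also lost when Control 1 and TAF15 OE 1 were both left out (log2 fold change -1.56, adjusted p = 0.152), and over all alternatives adjusted p ran from 6.39e-18 to 0.152.

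The immediate early genes, which neurons and other cells switch on within minutes of stimulation, went both ways. Of 32 tested, 6 fell and 3 rose, and adjusted over the list alone 9 fell and 4 rose. Beside Npas4, the phosphatase genes Dusp5 (-0.52) and Dusp6 (-0.39), the transcription factor genes Csrnp1 (-0.50) and Egr3 (-0.30) and the synaptic scaffold gene Homer1 (-0.32) were lower on the log2 scale. The stress-responsive factors Atf3 (1.16) and Maff (1.01) and the endothelial and lymphocyte factor Klf2 (0.84) were higher. Arc, a synaptic plasticity gene, stood at 225 ± 55.8 CPM in Control and 80.8 ± 35.7 in TAF15 OE (log2 fold change -1.48, SE 0.40) and did not pass the test (adjusted p = 0.0913), but did without TAF15 OE 3 (adjusted p = 0.0222) and with DESeq2 (adjusted p = 0.00350). Over all alternatives its adjusted p ran up to 0.388. Fos, a widely used activity marker, had a log2 fold change of 0.035 (SE 0.25, adjusted p = 0.947), and its sign turned without Control 2 (-0.16) or TAF15 OE 3 (-0.19). The list was lower by the list test (median -0.19, adjusted p = 0.0340, and adjusted p = 0.620 with an estimated correlation). Its mean log2 level, centred over the libraries, was 0.17, -0.16 and 0.24 in Control 1, 2 and 3. In TAF15 OE 1, 2 and 3 it was -0.13, -0.25 and 0.13, so the groups overlapped. The immediate early median was -0.33 without TAF15 OE 3 and 0.0080 under scaling on presynaptic genes. That scaling moves all genes together, and the list was still lower than the other genes by the list test (adjusted p = 1.59e-04). The late activity-response genes, induced hours after stimulation, were not called as a list (adjusted p = 0.466). Of 30 tested, 5 rose: Mfap3l (0.68), Baz1a (1.40), Blnk (1.01), Pim1 (1.24) and Sorcs1 (0.55). The 4 that fell were the neuropeptide precursor gene Vgf (-0.57), Nrn1 (-0.58), Sorcs3 (-0.33) and the synaptic pentraxin gene Nptx2 (-0.46), and adjusted over the list alone 5 rose and 5 fell. Dusp6, Egr3, Homer1, Maff, Klf2, Arc, Fos, Pim1, Sorcs1, Nrn1, Sorcs3 and Nptx2 were chosen after their values were seen. With libraries left out 1 at a time, the calls of Dusp5, Dusp6, Csrnp1, Egr3, Homer1, Atf3, Maff, Klf2, Sorcs1, Sorcs3, Nptx2 and the immediate early genes list were lost without Control 1. The calls of Csrnp1, Maff, Pim1, Sorcs3 and Nptx2 were lost without Control 2. The calls of Dusp5, Dusp6, Csrnp1, Egr3, Homer1, Atf3, Maff, Pim1, Sorcs1, Sorcs3 and the immediate early genes list were lost without Control 3. The calls of Dusp6, Maff, Klf2, Sorcs1 and the immediate early genes list were lost without TAF15 OE 1. The calls of Dusp5, Dusp6, Csrnp1, Egr3, Homer1, Atf3, Klf2, Sorcs1, Nrn1, Sorcs3, Nptx2 and the immediate early genes list were lost without TAF15 OE 2. The calls of Csrnp1, Egr3, Homer1, Atf3, Maff, Klf2, Pim1 and Nptx2 were lost without TAF15 OE 3, all at adjusted p of 0.0508 to 0.174. Dusp5, Csrnp1, Dusp6, Homer1, Egr3, Sorcs3 and Nptx2 were not called under scaling on presynaptic genes, at adjusted p of 0.0747 to 0.416. Dusp5, Dusp6, Maff, Klf2, Sorcs1, Sorcs3 and the immediate early genes list were not called without both Control 1 and TAF15 OE 1 (adjusted p of 0.0506 to 0.151). Egr3, Homer1 and Sorcs3 were not called with total counts (adjusted p of 0.0588 to 0.0616).

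**Figure D2:**
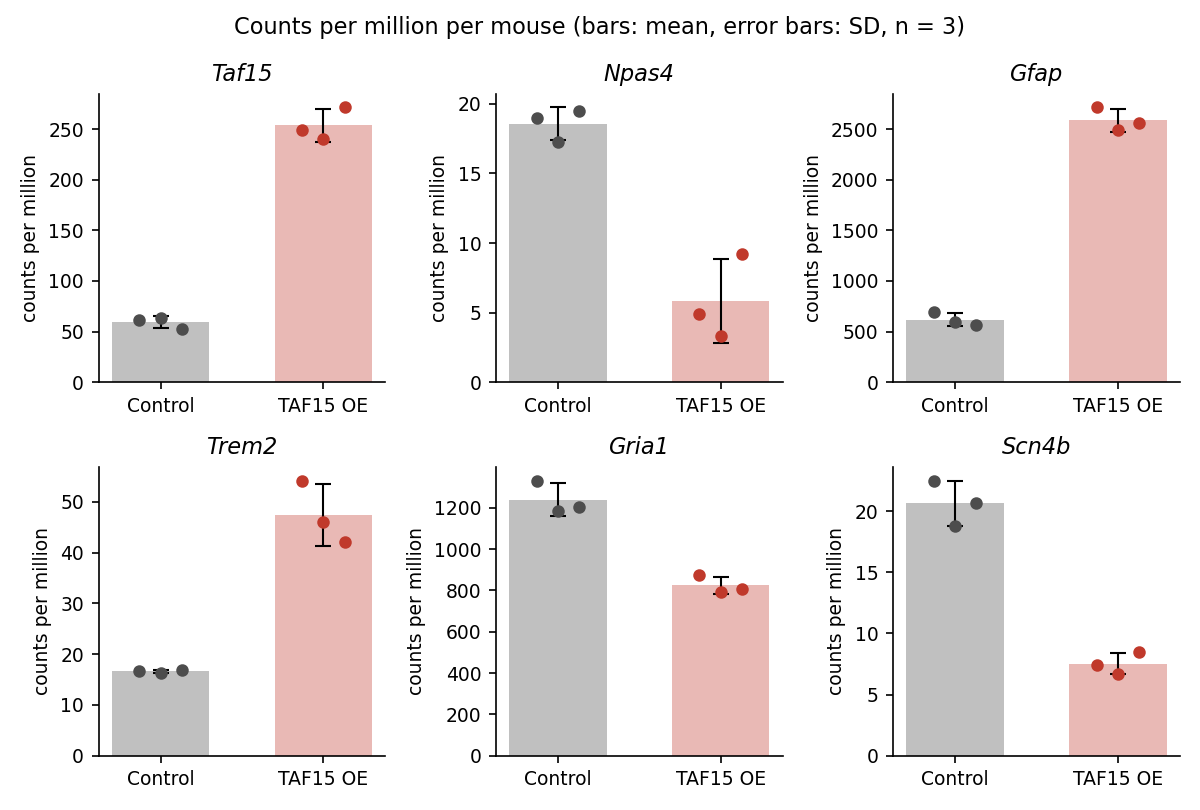
Levels (CPM) of 6 genes in each mouse (points), with the group mean (bars) and SD (error bars, n = 3), from 0. In all 6 panels the 3 TAF15 OE mice lie on 1 side of the 3 Control mice, higher for Taf15, Gfap and Trem2 and lower for Npas4, Gria1 and Scn4b.

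Across the transcriptome, the lists of glial, vascular and immune genes were higher in TAF15 OE by the list test and most lists of neuronal genes were lower, while the interneuron list was not called. In all, 34 of 49 tested lists passed, but with an estimated correlation limma's camera called 0, with 7 at an unadjusted p below 0.05, and fry called 17. The test called 2559 of 16758 genes, 1562 higher and 997 lower, so 61.0% of the calls were higher. With total counts as the only scaling, 72.0% were higher (1838 higher and 716 lower), and with scaling on presynaptic genes, which moved the median of all tested genes to 0.23 on the log2 scale, 95.3% were higher (4237 higher and 210 lower). The higher genes had a median log2 fold change of 0.72 and the lower genes of -0.36, and 534 genes rose but 23 fell by at least 1 on the log2 scale. Protein-coding genes made up 1496 of the higher and 966 of the lower genes. The groups did not overlap in 5799 genes (34.6% of those tested, against 10% by chance for 3 against 3), 2554 of them called. Leaving out Control 1, Control 2, Control 3 or TAF15 OE 2 left 1381, 1519, 1698 or 1331 calls. The higher genes then numbered 957, 877 and 966 without Control 1, Control 2 and TAF15 OE 2, and the lower genes 424, 642, 568, 365 and 624 without Control 1, Control 2, Control 3, TAF15 OE 2 and TAF15 OE 3. Without both Control 1 and TAF15 OE 1, 2214 genes were called, 1197 higher and 1017 lower, of which 1795 were among the 2559.

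**Figure D3:**
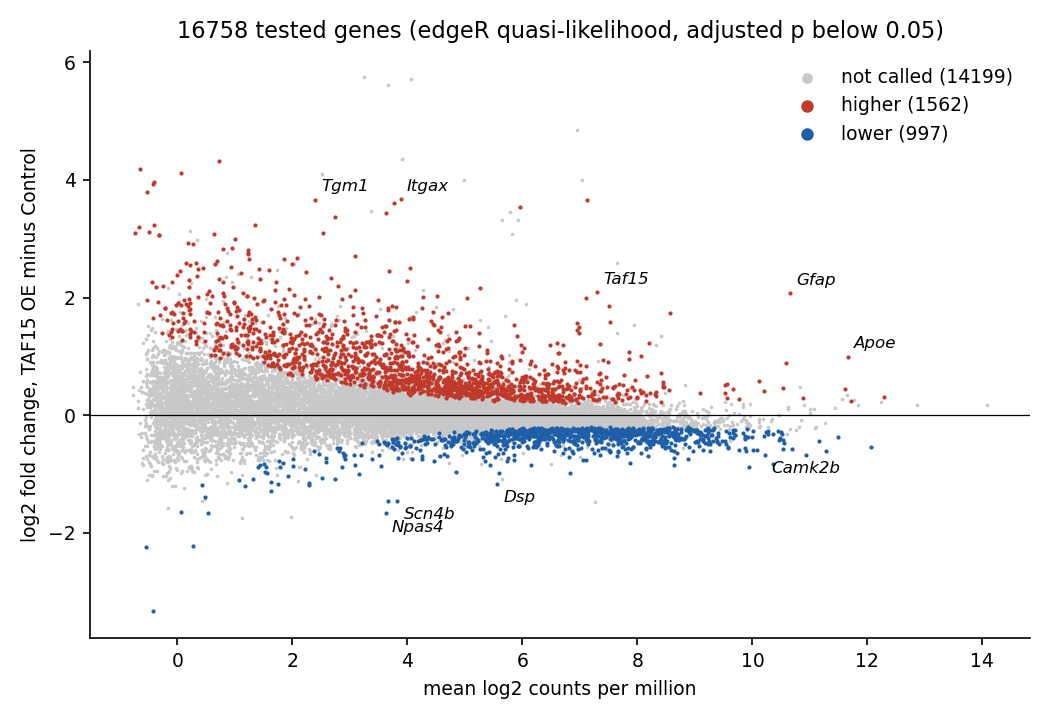
Log2 fold change (TAF15 OE minus Control) against mean log2 CPM for the 16758 tested genes, with the 1562 called higher in red, the 997 called lower in blue and the rest in grey. Higher calls reach above 3.5 at low and middle levels, and lower calls are mostly small and lie at middle and high levels; with scaling on presynaptic genes 95.3% of calls were higher.

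The 12 largest rises among genes with a mean log2 CPM of at least 1 and no overlap between groups lay between 2.70 and 3.68 on the log2 scale. Itgax, the integrin chain CD11c of activated microglia and dendritic cells, rose 12.8-fold, from 2.1 ± 0.380 to 26.9 ± 9.03 CPM (log2 fold change 3.68, SE 0.29, adjusted p = 3.45e-04). Cst7, a cystatin of activated microglia, rose by 3.43 on the log2 scale (SE 0.33), the neutrophil-attracting chemokine gene Cxcl5 by 3.36 (SE 0.23) and the sialic acid receptor gene Siglecf by 2.76 (SE 0.44). The immune receptor genes Cd300lf (3.24, SE 0.81) and Il2rb (2.74, SE 0.50), the latter a chain of the interleukin-2 receptor, rose too. Igha, the constant region of immunoglobulin A, stood at 20.4 ± 16.2 CPM in Control and 259 ± 105 in TAF15 OE (3.67, SE 0.74), and Mzb1, a chaperone of antibody-secreting cells, rose by 2.81 (SE 0.55). The central complement gene C3 rose by 3.54 (SE 0.71). The transglutaminase gene Tgm1 (3.67, SE 0.34), the oligodendrocyte protease gene Klk6 (3.10, SE 0.45) and the transporter gene Slc43a3 (2.70, SE 0.20) completed the 12. Clec7a, a receptor for fungal glucans carried by activated microglia, was passed over by the rule because its annotation is polymorphic pseudogene, and was chosen after its values were seen (3.61, SE 0.28, adjusted p = 2.81e-04). Of these, the calls of C3 and Cd300lf were lost without Control 1. The calls of Igha, C3, Cd300lf and Mzb1 were lost without Control 2 or Control 3. The call of Igha was lost without TAF15 OE 1. The calls of Igha and C3 were lost without TAF15 OE 2. The calls of Igha, C3 and Cd300lf were lost without TAF15 OE 3, all at adjusted p of 0.0522 to 0.170. Igha was not called without both Control 1 and TAF15 OE 1 (adjusted p = 0.111). C3 and Cd300lf were not called with limma-voom (adjusted p of 0.105 to 0.134). Igha and C3 were not called without a filter (adjusted p of 0.0693 to 0.0704). Cd300lf had a log2 fold change of 2.1 without TAF15 OE 1 and 2.15 without both Control 1 and TAF15 OE 1. On FPKM with a pseudocount of 1 several of these rises were smaller, among them Itgax (2.19), Tgm1 (1.75) and Siglecf (0.99), which stayed called. Il2rb (0.93) was not called there by limma-trend (adjusted p = 0.0574). As an immunoglobulin gene Igha shares sequence with its relatives, so that its counts are uncertain.

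The 12 largest falls, of which Npas4 was the first, were smaller than the largest rises. Scn4b, a beta subunit of neuronal sodium channels, stood at 20.6 ± 1.86 CPM in Control and 7.52 ± 0.870 in TAF15 OE and fell 2.74-fold (log2 fold change -1.45, SE 0.13, adjusted p = 1.49e-04). Slc26a10, of the anion transporter family, fell 2.76-fold (log2 fold change -1.46, SE 0.16), and the desmosome gene Dsp, which marks dentate granule neurons, fell 2.25-fold (-1.17, SE 0.18). Tdo2, an enzyme of tryptophan breakdown also found in granule neurons, fell by 1.18 on the log2 scale (SE 0.23). The signalling ligand genes Wnt2 (-1.13) and Wnt9a (-1.08), the RNA-binding ubiquitin ligase gene Trim71 (-1.28) and the transcription factor gene Mafa (-1.21) were lower, with SE between 0.28 and 0.32. So were Hpdl (-1.17), the protocadherin gene Pcdha7 (-1.10) and Tmem114 (-1.04). Pcdha7 shares its last exons with the other genes of its cluster, so its counts are uncertain. Among the falls, the calls of Trim71, Mafa, Hpdl, Wnt2 and Tmem114 were lost without Control 1. The calls of Hpdl, Pcdha7, Wnt9a and Tmem114 were lost without Control 2. The calls of Trim71, Mafa, Wnt2, Pcdha7 and Tmem114 were lost without Control 3. The call of Wnt9a was lost without TAF15 OE 1. The calls of Trim71, Mafa, Hpdl, Wnt2, Pcdha7, Wnt9a and Tmem114 were lost without TAF15 OE 2. The calls of Mafa, Hpdl, Pcdha7 and Tmem114 were lost without TAF15 OE 3, all at adjusted p of 0.0522 to 0.168. Scaling on presynaptic genes ended the calls of Pcdha7 (adjusted p = 0.0636) and Tmem114 (adjusted p = 0.0573). Wnt2 was not called without both Control 1 and TAF15 OE 1 (adjusted p = 0.0849). Pcdha7 was not called with DESeq2 (adjusted p = 0.0514). Pcdha7 was not called with limma-voom (adjusted p = 0.0503). Wnt9a had a log2 fold change of -0.71 without Control 2. Wnt2 (-0.59, adjusted p = 0.0770) and Wnt9a (-0.60, adjusted p = 0.107) were among the falls not called by limma-trend on FPKM with a pseudocount of 1.

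The list of genes of microglia, the resident immune cells of the brain, was higher by the list test. Of 26 tested microglia markers, 22 rose (24 adjusted over the list alone), with a median log2 fold change of 1.18. Among them the lipid-sensing receptor gene Trem2 rose 2.85-fold, from 16.6 ± 0.305 to 47.4 ± 6.15 CPM (log2 fold change 1.51, SE 0.11), the fractalkine receptor gene Cx3cr1 by 1.20 (SE 0.10) and the Trem2 adaptor gene Tyrobp by 1.18 (SE 0.13). The list was higher at adjusted p = 4.21e-14, and adjusted p = 0.370 with an estimated correlation. The disease-associated microglia genes, which microglia raise around plaques and injury, had 17 of 24 members higher (22 adjusted over the list alone) and a median of 1.33 (adjusted p = 4.21e-14, and adjusted p = 0.337 with an estimated correlation). They included the lipid carrier gene Apoe (1.00, SE 0.082), the lysosomal gene Cd68 (1.44, SE 0.13), Gpnmb (1.59, SE 0.15) and the tetraspanin gene Cd9 (1.19, SE 0.11). Of 15 complement components, 10 rose (13 adjusted over the list alone; median 1.39, adjusted p = 2.04e-08, and adjusted p = 0.370 with an estimated correlation). These included the complement inhibitor gene Serping1 (1.67, SE 0.16), the receptor gene C3ar1 (1.82, SE 0.25) and the protease gene C1s1 (1.93, SE 0.33). Of 16 inflammatory cytokines and chemokines, 6 rose (12 adjusted over the list alone), with a median of 0.94 (adjusted p = 4.56e-05, and adjusted p = 0.405 with an estimated correlation). The B cell attractant gene Cxcl13 rose by 2.44 (SE 0.28), the microglial growth factor gene Csf1 by 0.72 (SE 0.10), Tgfb1 by 0.88 and the adhesion gene Vcam1 by 0.73. Of 12 markers of perivascular macrophages and monocytes 3 rose, the monocyte gene Ly6c2 (1.97), which has near-identical relatives, Mgst1 (0.99) and the scavenger receptor gene Stab1 (0.45), as did 3 adjusted over the list alone (median 0.78, adjusted p = 0.0433, and adjusted p = 0.417 with an estimated correlation). Here the calls of Tgfb1, Mgst1 and Stab1 were lost without Control 1. The calls of Tgfb1, Vcam1 and Stab1 were lost without Control 2. The calls of Ly6c2, Mgst1 and Stab1 were lost without Control 3. The calls of Vcam1, Mgst1, Stab1 and the perivascular macrophage and monocyte markers list were lost without TAF15 OE 1. The calls of Mgst1 and Stab1 were lost without TAF15 OE 2. The call of Vcam1 was lost without TAF15 OE 3, all at adjusted p of 0.0529 to 0.201. The perivascular macrophage and monocyte markers list was not called under scaling on presynaptic genes, at adjusted p = 0.524. The cytokine and chemokine median was 0.62 without TAF15 OE 1 and 0.53 without both Control 1 and TAF15 OE 1. The macrophage and monocyte median was 0.25 without TAF15 OE 1 and 0.11 without both Control 1 and TAF15 OE 1. Tgfb1 had a log2 fold change of 0.55 without both Control 1 and TAF15 OE 1. Stab1 and the perivascular macrophage and monocyte markers list were not called without both Control 1 and TAF15 OE 1 (adjusted p of 0.165 to 0.568). The perivascular macrophage and monocyte markers list was not called with total counts (adjusted p = 0.0840). Stab1 was not called with limma-voom (adjusted p = 0.0517).

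The list of genes of reactive astrocytes, the state astrocytes take on after injury, was higher too. Of 30 tested, 21 rose (24 adjusted over the list alone), with a median log2 fold change of 1.28. The intermediate filament gene Gfap, the standard marker of this state, rose 4.2-fold, from 617 ± 66.1 to 2588 ± 114 CPM (log2 fold change 2.07, SE 0.090, adjusted p = 4.97e-07). The asparaginase gene Aspg rose by 2.46 (SE 0.17), the oncostatin M receptor gene Osmr by 2.03 (SE 0.15) and the lipid receptor gene S1pr3 by 1.74 (SE 0.12). The list was higher at adjusted p = 4.71e-14, and adjusted p = 0.243 with an estimated correlation. Of 22 markers that astrocytes also carry at rest 13 rose (15 adjusted over the list alone), with a median of 0.37 (adjusted p = 1.62e-06, and adjusted p = 0.294 with an estimated correlation). They included the water channel gene Aqp4 (1.23, SE 0.11), the secreted chaperone gene Clu (0.88, SE 0.072), the gap junction gene Gja1 (0.66, SE 0.083) and Mlc1 (0.60, SE 0.073). The astrocyte marker median was 0.58 under scaling on presynaptic genes.

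Lists of lymphocyte and antigen presentation genes were higher by the list test, at unequal levels in the 3 TAF15 OE mice. Of 21 T and NK cell markers 14 rose (18 adjusted over the list alone; median 1.94), among them the inhibitory receptor gene Pdcd1 (2.90, SE 0.47), the T cell receptor constant gene Trac (2.08, SE 0.36), Cd6 (2.08, SE 0.36) and Ms4a4b (1.67, SE 0.28). The list was higher at adjusted p = 4.79e-09, and adjusted p = 0.374 with an estimated correlation, and its mean centred log2 level was 1.45 in TAF15 OE 1, 0.27 in TAF15 OE 2 and 0.67 in TAF15 OE 3. Of 10 B and plasma cell markers 5 rose, which were the transcriptional coactivator gene Pou2af1 (3.08, SE 0.53), the B cell receptor chain genes Cd79a (2.02, SE 0.41) and Cd79b (1.81, SE 0.46; chosen after its values were seen), Mzb1 and the light chain gene Iglc2. Adjusted over the list alone 7 rose, and the median was 2.30 (adjusted p = 4.60e-05, and adjusted p = 0.386 with an estimated correlation). Iglc2 rested on 2, 0 and 1 counts in Control 1, 2 and 3 and 11, 15 and 28 in TAF15 OE 1, 2 and 3, and has near-identical relatives. The mean centred level of the B and plasma cell list was 0.17 in Control 1, against -1.82 and -1.91 in Control 2 and 3. In TAF15 OE 1, 2 and 3 it was 0.16, 1.45 and 1.95, so TAF15 OE 1 did not lie above Control 1. Of 8 MHC class II genes, which present antigen to helper T cells, 1 rose by the all-gene test, H2-DMb1 (1.70, SE 0.44), and 7 adjusted over the list alone. The median was 2.79 (adjusted p = 8.19e-04, and adjusted p = 0.448 with an estimated correlation), and the mean centred level was 2.42 in TAF15 OE 1 against -0.086 and 0.83 in TAF15 OE 2 and 3. Cd74 had a log2 fold change of 4.0 (SE 1.11, adjusted p = 0.0998), H2-Oa of 2.27 (adjusted p = 0.0797) and H2-DMa of 0.72 (adjusted p = 0.0684). Cd74 passed without TAF15 OE 1 (2.49, adjusted p = 0.0242), H2-DMa and H2-Oa without TAF15 OE 2 (adjusted p = 0.00652 and 0.0181) and H2-DMa with total counts (adjusted p = 0.0491). Over the alternatives other than scaling on presynaptic genes, adjusted p ran from 4.51e-04 to 0.265 for Cd74. It ran from 5.90e-07 to 0.281 for H2-Oa and from 1.97e-06 to 0.197 for H2-DMa. Their log2 fold changes ran from 2.49 to 4.46, 0.99 to 2.68 and 0.43 to 0.93. Of 31 interferon-gamma and MHC class I genes 4 rose (7 adjusted over the list alone), H2-M3 (1.18), the interferon-induced GTPase genes Gbp5 (1.67) and Gbp6 (1.47) and the immunoproteasome gene Psmb8 (1.30), with a list median of 1.25 (adjusted p = 8.59e-08, and adjusted p = 0.455 with an estimated correlation). Of 34 type I interferon response genes 3 rose, Sp100 (1.33), Ifi204 (1.44) and the RNA sensor gene Dhx58 (0.93), as did 3 adjusted over the list alone. That list's median was 0.50 (adjusted p = 0.00462, and adjusted p = 0.690 with an estimated correlation), and without Control 1 and TAF15 OE 1 the list test turned to lower (adjusted p = 0.854). Its mean centred level was -0.85, -0.18 and 0.20 in Control 1, 2 and 3 and 0.68, -0.28 and 0.44 in TAF15 OE 1, 2 and 3, so the groups overlapped. The H2 and Gbp genes and Ifi204 have close relatives, so their counts are uncertain. In this group the calls of Cd79b, H2-DMb1, H2-M3, Gbp5, Gbp6, Psmb8, Ifi204, Dhx58 and the type I interferon response list were lost without Control 1. The calls of Mzb1, H2-DMb1, Gbp5, Gbp6, Psmb8, Sp100, Ifi204 and Dhx58 were lost without Control 2. The calls of Cd79b, Mzb1, H2-DMb1, H2-M3, Gbp5, Gbp6, Psmb8 and Ifi204 were lost without Control 3. The calls of Cd79b, Dhx58 and the type I interferon response list were lost without TAF15 OE 1. The calls of H2-DMb1, Gbp5, Gbp6, Psmb8, Ifi204 and Dhx58 were lost without TAF15 OE 3, all at adjusted p of 0.0522 to 0.312. The type I interferon response list was not called under scaling on presynaptic genes, at adjusted p = 0.524. The B and plasma cell median was 4.36 without Control 1 and 4.33 without both Control 1 and TAF15 OE 1. The MHC class II median was 1.58 without TAF15 OE 1 and 1.69 without both Control 1 and TAF15 OE 1. The interferon-gamma and MHC class I median was 0.68 without TAF15 OE 1 and 0.54 without both Control 1 and TAF15 OE 1. The type I interferon median was 0.26 without Control 1, 0.75 without Control 3, 0.29 without TAF15 OE 1 and 0.047 without both Control 1 and TAF15 OE 1. H2-DMb1 had a log2 fold change of 1.01 without both Control 1 and TAF15 OE 1. Gbp6 had a log2 fold change of 0.92 without TAF15 OE 1 and 0.77 without both Control 1 and TAF15 OE 1. Psmb8 had a log2 fold change of 0.81 without TAF15 OE 1 and 0.77 without both Control 1 and TAF15 OE 1. Ifi204 had a log2 fold change of 0.92 without both Control 1 and TAF15 OE 1. Cd79b, H2-M3, Gbp6, Psmb8 and Dhx58 were not called without both Control 1 and TAF15 OE 1 (adjusted p of 0.0588 to 0.123). Gbp6 and Psmb8 were not called with the size factors of DESeq2 (adjusted p of 0.0520 to 0.0549). Iglc2 was not called with DESeq2 (adjusted p = NA). H2-DMb1, Gbp5, Gbp6, Psmb8 and Ifi204 were not called with limma-voom (adjusted p of 0.0817 to 0.121). Gbp5 was not called without a filter (adjusted p = 0.112).

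Lists of oligodendrocyte, vessel and fibroblast genes were higher too by the list test. Of 25 oligodendrocyte and myelin genes 13 rose (20 adjusted over the list alone), including the lipocalin gene Apod (1.07, SE 0.11), Tspan2 (0.62, SE 0.090), the myelin adhesion gene Mag (0.53, SE 0.090) and the myelin tight junction gene Cldn11 (0.49, SE 0.089), and the median was 0.43 (adjusted p = 2.65e-07, and adjusted p = 0.405 with an estimated correlation). Of 15 markers of their precursors, 2 rose, the matrix gene Vcan (0.49) and the phosphatase gene Ptprz1 (0.35), as did 2 adjusted over the list alone (median 0.33, adjusted p = 0.00410, and adjusted p = 0.294 with an estimated correlation). Of 23 endothelial markers 10 rose (14 adjusted over the list alone; median 0.49, adjusted p = 1.52e-05, and adjusted p = 0.396 with an estimated correlation), among them the lactate transporter gene Slc16a1 (0.66), Ly6a (1.02), which has close relatives, the efflux pump gene Abcb1a (0.51) and Pecam1 (0.59). Of 14 mural cell markers 8 rose (10 adjusted over the list alone; median 0.59, adjusted p = 8.63e-05, and adjusted p = 0.35 with an estimated correlation), among them Atp13a5 (0.67), the myosin light chain gene Myl9 (0.70), Notch3 (0.71) and Cnn1 (2.18). Of 22 markers of meningeal and vascular fibroblasts 6 rose (14 adjusted over the list alone; median 0.65, adjusted p = 3.15e-06, and adjusted p = 0.405 with an estimated correlation), among them the matrix genes Bgn (1.08), Col1a1 (0.78), Fmod (1.25) and Vtn (0.54). Of 17 ependymal markers 2 rose, Tm4sf1 (0.75) and the cilia factor gene Foxj1 (0.72), as did 2 adjusted over the list alone (median 0.42, adjusted p = 0.0342, and adjusted p = 0.620 with an estimated correlation), and the mean centred level was -0.66 in Control 1 against 0.088 and -0.045 in Control 2 and 3. For these lists the call of the ependymal cell markers list was lost without Control 1. The calls of Pecam1, Fmod, Vtn and Foxj1 were lost without Control 2. The call of Cnn1 was lost without Control 3. The call of Foxj1 was lost without TAF15 OE 1 or TAF15 OE 3. The calls of Foxj1 and the ependymal cell markers list were lost without TAF15 OE 2, all at adjusted p of 0.0522 to 0.225. The ependymal cell markers list was not called under scaling on presynaptic genes, at adjusted p = 0.524. The precursor median was 0.21 without TAF15 OE 1 and 0.53 under scaling on presynaptic genes. The endothelial median was 0.29 without both Control 1 and TAF15 OE 1. The ependymal median was 0.17 without Control 1 and 0.25 without TAF15 OE 2. The mean centred ependymal level was -0.14 in TAF15 OE 1, below Control 2 and 3, so the groups overlapped. Abcb1a had a log2 fold change of 0.34 without both Control 1 and TAF15 OE 1. Pecam1 had a log2 fold change of 0.38 without both Control 1 and TAF15 OE 1. Abcb1a and Pecam1 were not called without both Control 1 and TAF15 OE 1 (adjusted p of 0.0570 to 0.0578). The ependymal cell markers list was not called with total counts (adjusted p = 0.0824).

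Lists of neuronal genes were lower by the list test, for both sides of the synapse and for ion channels. Of 34 genes for ionotropic glutamate receptors and the excitatory postsynaptic scaffold, 19 fell (21 adjusted over the list alone), with a median log2 fold change of -0.33 (adjusted p = 1.36e-08, and adjusted p = 0.370 with an estimated correlation). The AMPA receptor gene Gria1 fell 1.5-fold, from 1239 ± 80.0 to 824 ± 42.5 CPM (log2 fold change -0.59, SE 0.076, adjusted p = 9.54e-04), the NMDA receptor gene Grin1 fell by 0.45 (SE 0.060), the kinase gene Camk2b fell by 0.67 (SE 0.093) and the AMPA receptor auxiliary gene Cacng8 fell by 0.65 (SE 0.091). Of 35 genes of the presynaptic release machinery 18 fell (19 adjusted over the list alone), among them the calcium sensor gene Syt7 (-0.55, SE 0.089), the vesicular glutamate transporter gene Slc17a7 (-0.48, SE 0.083), the priming factor gene Unc13a (-0.41, SE 0.071) and the vesicle GTPase gene Rab3a (-0.36, SE 0.063), while Sypl, a vesicle protein gene also used outside neurons and chosen after its values were seen, rose (0.34). The list's median was -0.26 (adjusted p = 2.34e-08, and adjusted p = 0.243 with an estimated correlation). Of 36 voltage-gated ion channel genes 14 fell (16 adjusted over the list alone; median -0.22, adjusted p = 2.37e-08, and adjusted p = 0.374 with an estimated correlation), among them Scn4b, the potassium channel gene Kcnd2 (-0.57, SE 0.081), the sodium channel gene Scn8a (-0.47, SE 0.085) and the calcium channel gene Cacna1i (-0.45, SE 0.091). Of 18 genes for GABA receptors and the inhibitory postsynapse 7 fell (9 adjusted over the list alone; median -0.21, adjusted p = 5.49e-04, and adjusted p = 0.374 with an estimated correlation), among them Gabra5 (-0.43) and Gabbr2 (-0.46), while Gabrg1, a subunit also made by glia, rose (0.55). Of 16 markers of CA1 pyramidal neurons, the field injected, 4 fell (5 adjusted over the list alone), the transcription factor gene Pou3f1 (-0.85, SE 0.092), Fibcd1 (-0.46, SE 0.071), the calcium-binding gene Cabp1 (-0.46, SE 0.089) and Spink8 (-0.75, SE 0.15), with a median of -0.26 (adjusted p = 7.59e-04, and adjusted p = 0.370 with an estimated correlation). Of 18 dentate granule neuron markers 7 fell (8 adjusted over the list alone), among them Fam163b (-0.70), Lct (-0.98), the calcium buffer gene Calb1 (-0.57) and Dsp. The median was -0.13 (adjusted p = 0.00134, and adjusted p = 0.455 with an estimated correlation). Of 15 CA3 pyramidal neuron markers 2 fell, the granin gene Chgb (-0.52) and Ociad2 (-0.26), as did 2 adjusted over the list alone; the median was -0.17 (adjusted p = 0.0342, and adjusted p = 0.396 with an estimated correlation). In the same libraries microglia and astrocyte markers had medians of 1.18 and 0.37. Under scaling on presynaptic genes the medians were -0.13 for glutamate receptors, -0.059 for the release machinery, -0.020 for voltage-gated channels and -0.0046 for GABA receptors. The CA1 median was -0.42 without TAF15 OE 3 and -0.061 under scaling on presynaptic genes. The dentate granule median was 0.0010 without Control 1, -0.20 without Control 2, -0.21 without Control 3, -0.34 without TAF15 OE 1, -0.065 without TAF15 OE 3, -0.24 without both Control 1 and TAF15 OE 1, -0.081 with total counts and 0.075 under scaling on presynaptic genes. The CA3 median was -0.11 without Control 1 and 0.027 under scaling on presynaptic genes. All of these neuronal lists were still lower by the list test under that scaling (adjusted p of 2.96e-11 to 0.0101). The mean centred level of the CA3 list was 0.030 in Control 2 and 0.043 in TAF15 OE 1, so the groups overlapped. Unc13a, Rab3a, Cacna1i, Chgb and Ociad2 were not called under scaling on presynaptic genes, at adjusted p of 0.0522 to 0.589. Among neuronal genes the calls of Sypl, Chgb, Ociad2 and the CA3 pyramidal neuron markers list were lost without Control 1. The calls of Chgb and Ociad2 were lost without Control 2. The calls of Sypl and Chgb were lost without Control 3. The call of Ociad2 was lost without TAF15 OE 1. The calls of Sypl, Gabrg1, Chgb, Ociad2 and the CA3 pyramidal neuron markers list were lost without TAF15 OE 2. The calls of Sypl, Ociad2, the dentate granule neuron markers list and the CA3 pyramidal neuron markers list were lost without TAF15 OE 3, all at adjusted p of 0.0561 to 0.136. Ociad2 was not called without both Control 1 and TAF15 OE 1 (adjusted p = 0.156). Ociad2 was not called with total counts (adjusted p = 0.0883).

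Among lists of metabolism, stress and cell state, the p53 response list was higher and the cholesterol biosynthesis list lower by the list test. Of 20 p53 response genes 7 rose (10 adjusted over the list alone; median 0.31, adjusted p = 7.59e-05, and adjusted p = 0.243 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose 2.47-fold (log2 fold change 1.30, SE 0.15), Trp53inp1 2.47-fold (1.30, SE 0.095), the death receptor family gene Eda2r 6.27-fold (2.65, SE 0.35) and Phlda3 1.74-fold (0.80, SE 0.10). Of 23 cholesterol biosynthesis genes 10 fell (16 adjusted over the list alone; median -0.37, adjusted p = 2.04e-08, and adjusted p = 0.374 with an estimated correlation), among them Fdft1 (-0.45), Msmo1 (-0.52) and the pathway's regulator Srebf2 (-0.32). Of 68 nuclear-encoded oxidative phosphorylation genes 9 fell (7 adjusted over the list alone), among them Ndufb2 (-0.57), Cox7b (-0.30), Cox8a (-0.30) and Cox6a1 (-0.24). The median was -0.18 (adjusted p = 8.75e-11, and adjusted p = 0.426 with an estimated correlation). Of 13 transcripts encoded in the mitochondrial genome 2 rose, mt-Nd5 (0.31) and mt-Nd6 (0.28), which have nuclear copies, and 3 adjusted over the list alone (median 0.22, adjusted p = 0.0260, and adjusted p = 0.620 with an estimated correlation). The share of counts from these transcripts was 4.50%, 4.41% and 4.23% in Control 1, 2 and 3 and 4.87%, 5.56% and 5.02% in TAF15 OE 1, 2 and 3. Of 8 replication-dependent histone genes 3 rose, Hist1h1d (3.00), Hist1h1c (1.54) and Hist1h2bc (0.49), as did 3 adjusted over the list alone (median 0.79, adjusted p = 0.00462, and adjusted p = 0.428 with an estimated correlation); histone genes have near-identical copies, so their counts are uncertain. Of 74 cytosolic ribosomal protein genes 1 rose, Rps20 (0.29), and the median was 0.093 (adjusted p = 0.0281, and adjusted p = 0.787 with an estimated correlation). Adjusted over the list alone edgeR called 0 of them, with 7 at an unadjusted p below 0.05. The mean centred level of this list was 0.067 in Control 2, above 0.052 and -0.039 in TAF15 OE 2 and 3, so the groups overlapped. Of 23 neuropeptide and granin genes 6 fell (8 adjusted over the list alone), among them Vgf, the cholecystokinin gene Cck (-0.58, SE 0.077) and Scg5 (-0.40), while the granin gene Scg3 rose (0.40). The median was -0.11 (adjusted p = 0.0474, and adjusted p = 0.535 with an estimated correlation). In that list TAF15 OE 2 (mean centred level 0.092) lay above Control 1 (0.053) and Control 3 (-0.087), so the groups overlapped. Of 18 heat shock protein genes Dnajb5 fell (-0.69, SE 0.10) and the small heat shock gene Hspb8 rose (0.56, SE 0.11), and adjusted over the list alone 5 fell and 1 rose. The median was -0.16 (adjusted p = 0.0366, and adjusted p = 0.534 with an estimated correlation). The highest mean centred level of the heat shock list was 0.14, in TAF15 OE 1, so the groups overlapped. For this set the calls of Cox8a, Cox6a1, Hist1h2bc, Rps20, the cytosolic ribosomal proteins list and the neuropeptides and granins list were lost without Control 1. The calls of Msmo1, Ndufb2, Cox7b, Cox8a, Cox6a1, mt-Nd5, mt-Nd6, Hist1h2bc, Scg5, the mitochondrially encoded transcripts list and the neuropeptides and granins list were lost without Control 2. The calls of Cox6a1, mt-Nd5, mt-Nd6, Hist1h2bc, Rps20, the mitochondrially encoded transcripts list and the cytosolic ribosomal proteins list were lost without Control 3. The calls of Hist1h2bc, Rps20, the cytosolic ribosomal proteins list and the neuropeptides and granins list were lost without TAF15 OE 1. The calls of Srebf2, Ndufb2, Cox6a1, mt-Nd5, mt-Nd6, Hist1h2bc, Rps20, the mitochondrially encoded transcripts list, the cytosolic ribosomal proteins list and the heat shock proteins list were lost without TAF15 OE 2. The calls of Cox8a, Cox6a1, mt-Nd5, mt-Nd6, Rps20, the neuropeptides and granins list and the heat shock proteins list were lost without TAF15 OE 3, all at adjusted p of 0.0502 to 0.717. Ndufb2, Cox7b, Cox8a, Cox6a1, Fdft1, Msmo1, Srebf2, Scg5 and the replication-dependent histones list were not called under scaling on presynaptic genes, at adjusted p of 0.0606 to 0.662. The p53 response median was 0.51 under scaling on presynaptic genes. The cholesterol median was -0.17 under scaling on presynaptic genes. The oxidative phosphorylation median was 0.021 under scaling on presynaptic genes. The mitochondrial transcript median was 0.10 without TAF15 OE 2 and 0.43 under scaling on presynaptic genes. The histone median was 0.46 without TAF15 OE 1 and 0.45 without both Control 1 and TAF15 OE 1. The ribosomal protein median was 0.14 without Control 2, 0.047 without Control 3, 0.030 without TAF15 OE 1, 0.017 without both Control 1 and TAF15 OE 1 and 0.29 under scaling on presynaptic genes. The neuropeptide and granin median was -0.025 without Control 2, -0.012 without TAF15 OE 1, -0.21 without TAF15 OE 2, -0.030 without both Control 1 and TAF15 OE 1, -0.063 with total counts and 0.088 under scaling on presynaptic genes. The heat shock median was -0.27 without both Control 1 and TAF15 OE 1 and 0.040 under scaling on presynaptic genes. The cholesterol, oxidative phosphorylation, neuropeptide and heat shock lists were still lower by the list test under that scaling (adjusted p of 1.74e-10 to 0.0155). Hist1h2bc had a log2 fold change of 0.29 without TAF15 OE 1 and 0.29 without both Control 1 and TAF15 OE 1. Hspb8 had a log2 fold change of 0.37 without both Control 1 and TAF15 OE 1. Hist1h2bc, Rps20, the cytosolic ribosomal proteins list and the neuropeptides and granins list were not called without both Control 1 and TAF15 OE 1 (adjusted p of 0.0761 to 0.968). mt-Nd5, mt-Nd6, Rps20, the cytosolic ribosomal proteins list and the neuropeptides and granins list were not called with the size factors of DESeq2 (adjusted p of 0.0574 to 0.0634). Cox7b and Cox6a1 were not called with total counts (adjusted p of 0.0523 to 0.0642). Rps20 was not called with DESeq2 (adjusted p = 0.0726). The cytosolic ribosomal proteins list was not called without a filter (adjusted p = 0.231). The neuropeptides and granins list was not called at a mean of at least 1 CPM (adjusted p = 0.0548).

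**Figure D4:**
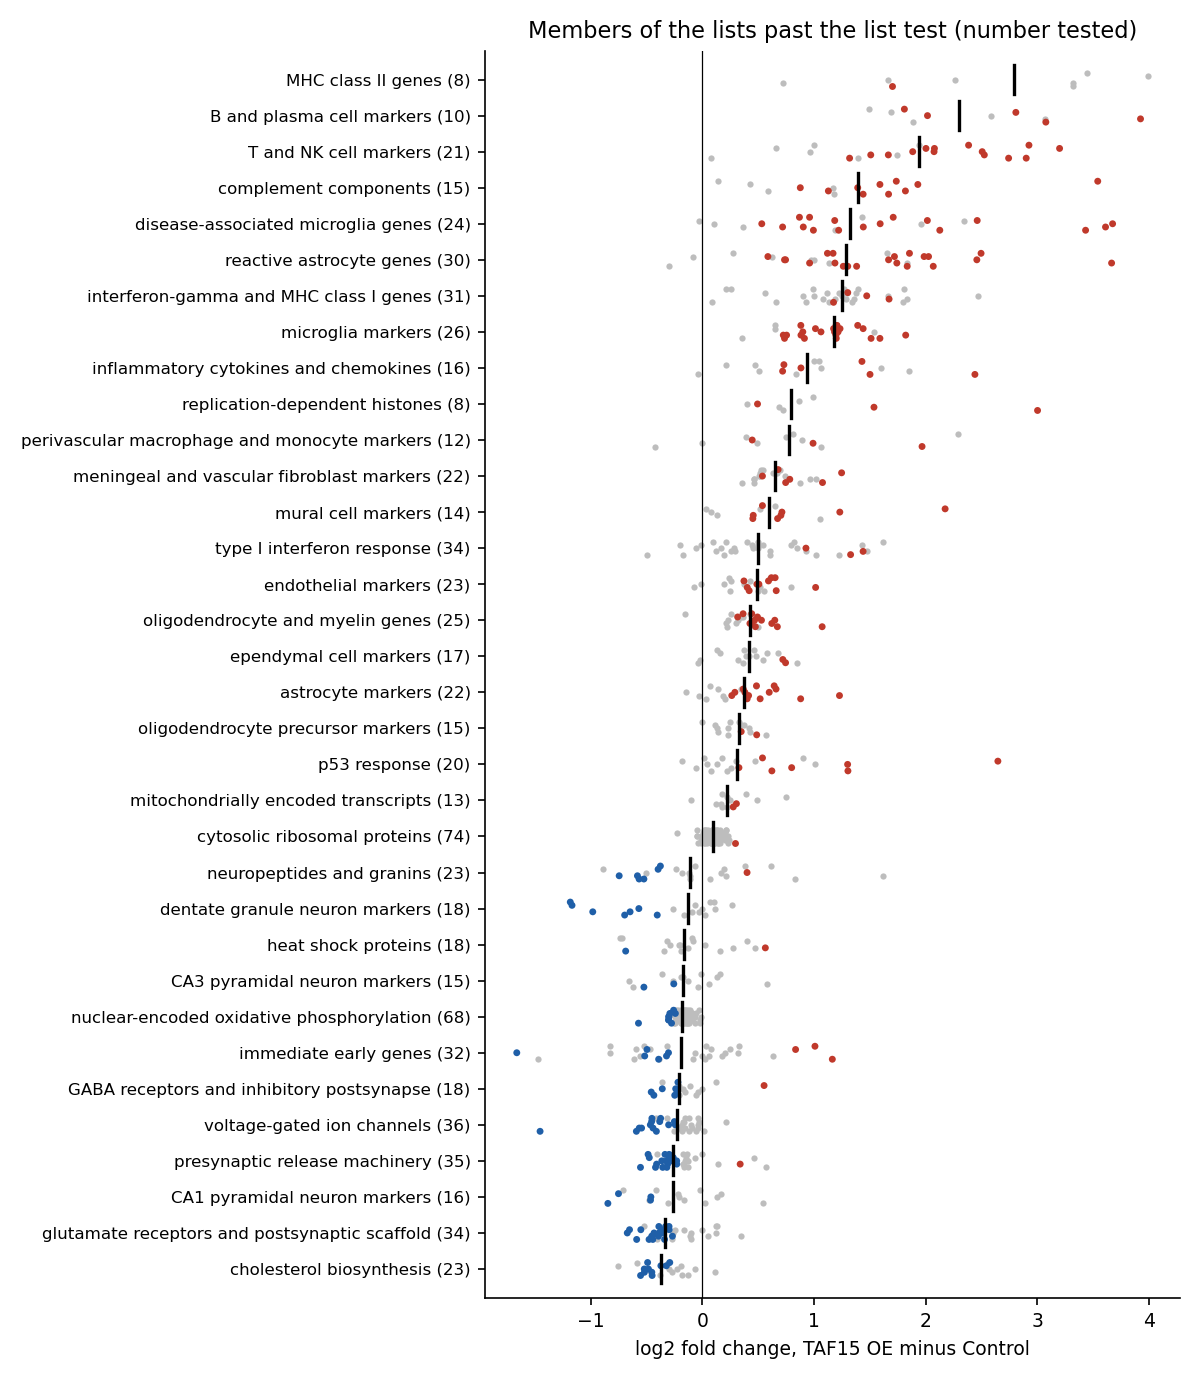
Log2 fold change (TAF15 OE minus Control) of every tested member of the 34 lists past the list test, with members called higher in red, called lower in blue and not called in grey, and each list's median as a black bar; the number of tested members follows each name. Medians of microglia (1.18) and reactive astrocyte genes (1.28) lie above 0 and those of glutamate receptor (-0.33) and presynaptic genes (-0.26) below it. Those of the oxidative phosphorylation, dentate, immediate early, CA3, heat shock and neuropeptide lists were above 0 under scaling on presynaptic genes. These lists were still lower by the list test there.

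A further 15 lists did not pass the list test. Their called members were chosen after their values were seen. Among 32 paraspeckle and splicing factor genes (list adjusted p = 0.134), the paraspeckle RNA gene Neat1 (1.20, SE 0.14) and the splicing repressor gene Ptbp1 (0.45) rose, and the neuronal splicing factor genes Rbfox3 (-0.50), Rbfox1 (-0.50) and Celf2 (-0.23) fell. Among 15 TFIID subunit genes (adjusted p = 0.334), Taf13 rose (0.40) and Taf5 fell (-0.56). Among 24 interneuron markers (adjusted p = 0.107), Pvalb (-0.48), Sst (-0.38) and Lamp5 (-0.37) fell and Sox6 (0.53) rose. Among 16 apoptosis and axonal injury genes (adjusted p = 0.204), the death receptor gene Fas (1.09), Casp8 (0.98), Sox11 (0.69) and Atf3 rose and Hrk (-0.74), Stmn2 (-0.26) and Nts (-0.75) fell. Among 15 adult neurogenesis genes (adjusted p = 0.214), Sox11 and Hopx (0.44) rose and Tubb3 fell (-0.35). Among 20 hypoxia and glycolysis genes (adjusted p = 0.525), Car9 (1.88), Hk2 (0.76), Ndrg1 (0.43) and Hif1a (0.30) rose and Slc2a3 (-0.26), Pgam1 (-0.22), Aldoa (-0.28) and Higd1a (-0.30) fell. Among 27 genes of the endoplasmic reticulum and integrated stress response (adjusted p = 0.624), Dnajc3 rose (0.33) and Atf4 (-0.35) and Asns (-0.36) fell. Among 17 glucocorticoid-responsive genes (adjusted p = 0.461), Cdkn1a and Mt1 (0.70) rose, and among 18 circadian clock genes (adjusted p = 0.997) Bhlhe41 did (0.73). Markers of neighbouring tissue that a dissection could include were also measured. Among 18 thalamus and habenula markers (adjusted p = 0.104), Lef1 (0.83), Synpo2 (0.79) and Tcf7l2 (0.76) rose. Among 16 striatum markers (adjusted p = 0.840), Drd1 (1.84) and Rxrg (0.69) rose and Pde10a fell (-0.41). Among 23 neocortex markers (adjusted p = 0.966), Stard8 (0.61) and Rorb (0.54) rose and Hs3st4 (-0.51), Lmo3 (-0.50) and Lamp5 fell. The 24 choroid plexus markers had a median of 0.34 (adjusted p = 0.154), and their mean centred level was -2.92 in Control 1 against 0.67 and 0.85 in Control 2 and 3. The 6 erythrocyte transcripts had a median of 0.10 (adjusted p = 0.892). The 4 sex-linked genes were too few for the list test and had a median of -0.11. The median had the opposite sign to the list test in the glucocorticoid, striatum, neocortex and circadian lists, and in the late activity and hypoxia lists the mean was above 0 with median and test below. Of the genes in these lists the calls of Ptbp1, Rbfox1, Celf2, Taf13, Taf5, Pvalb, Lamp5, Atf3, Stmn2, Nts, Car9, Hif1a, Slc2a3, Pgam1, Aldoa, Higd1a, Dnajc3, Mt1, Lef1, Tcf7l2, Drd1, Rxrg and Lmo3 were lost without Control 1. The calls of Rbfox1, Celf2, Taf13, Taf5, Pvalb, Sst, Lamp5, Sox6, Sox11, Stmn2, Nts, Hopx, Slc2a3, Pgam1, Aldoa, Higd1a, Lef1, Tcf7l2, Drd1, Rxrg, Rorb and Lmo3 were lost without Control 2. The calls of Ptbp1, Rbfox1, Celf2, Taf13, Taf5, Sox11, Atf3, Nts, Hopx, Car9, Slc2a3, Pgam1, Aldoa, Lef1, Tcf7l2, Drd1, Rxrg and Pde10a were lost without Control 3. The calls of Taf13, Taf5, Nts, Slc2a3, Higd1a and Mt1 were lost without TAF15 OE 1. The calls of Rbfox1, Celf2, Taf13, Taf5, Lamp5, Sox6, Sox11, Atf3, Stmn2, Nts, Hopx, Car9, Hif1a, Slc2a3, Pgam1, Aldoa, Higd1a, Dnajc3, Mt1, Lef1, Tcf7l2, Drd1, Rxrg, Pde10a and Rorb were lost without TAF15 OE 2. The calls of Ptbp1, Rbfox1, Celf2, Taf5, Pvalb, Atf3, Stmn2, Nts, Hopx, Hif1a, Pgam1, Aldoa, Higd1a, Lef1, Rxrg and Rorb were lost without TAF15 OE 3, all at adjusted p of 0.0508 to 0.178. Sst, Nts, Lamp5, Pvalb, Celf2, Rbfox1, Stmn2, Tubb3, Taf5, Slc2a3, Pgam1, Aldoa, Higd1a, Atf4, Asns, Pde10a and Lmo3 were not called under scaling on presynaptic genes, at adjusted p of 0.0883 to 0.840. Tcf7l2 had a log2 fold change of 0.46 without TAF15 OE 2. Drd1 had a log2 fold change of 1.18 without both Control 1 and TAF15 OE 1. Ptbp1, Taf13, Pvalb, Lamp5, Nts, Slc2a3, Higd1a, Dnajc3, Mt1, Lef1, Synpo2 and Rxrg were not called without both Control 1 and TAF15 OE 1 (adjusted p of 0.0529 to 0.177). Celf2, Taf5, Nts, Slc2a3, Pgam1, Aldoa and Higd1a were not called with total counts (adjusted p of 0.0547 to 0.0916). Taf5, Nts and Rxrg were not called with DESeq2 (adjusted p of 0.0505 to 0.0601). Taf5, Higd1a, Tcf7l2 and Drd1 were not called with limma-voom (adjusted p of 0.0515 to 0.0684). Taf5 was not called at a mean of at least 1 CPM (adjusted p = 0.0537).

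Of the 34 lists that passed the list test, 22 were higher and 12 lower, and with an estimated correlation the smallest adjusted p was 0.243. By fry, which asks whether the genes of a list moved on balance 1 way and does not compare them with other genes, 17 lists passed, 16 of them among the 34, and by its mixed test of change in either direction 38 passed. The authors' own table gives the same comparison for 30821 genes. It holds 2737 genes with an adjusted p below 0.05, 1452 higher and 1285 lower, and 2269 of them were called here in the same direction. It marks 558 genes, 531 higher and 27 lower, which are those that also have an absolute log2 fold change above 1; 540 of them were tested here and 468 called in the same direction. In that table Taf15 has a log2 fold change of 2.07 (adjusted p = 1.03e-100), Npas4 of -1.70 (adjusted p = 1e-08), Arc of -1.51 (adjusted p = 0.0036) and Ewsr1 of -0.01 (adjusted p = 0.98).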

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

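Leaving out Control 1 and TAF15 OE 1 together and scaling on presynaptic genes were chosen after the data were seen; the other alternatives were planned. Taf15 kept its direction and its call under every alternative run on it, at log2 fold changes of 2.02 to 2.30. Npas4 was lower under all of them, at -2.17 to -1.28, with each library left out between -2.17 and -1.41, and lost its call without Control 1, 2 or 3 or TAF15 OE 1. It also lost it without both Control 1 and TAF15 OE 1 (-1.56, adjusted p = 0.152; range over its alternatives 6.39e-18 to 0.152); the cause was not tested. The count of 2559 called genes, 1562 higher and 997 lower, stayed within 1.5 times with DESeq2 (2749 calls, 2269 of them shared), limma-voom (2418), the size factors of DESeq2 (2557), total counts (2554), a mean of at least 1 CPM (2508), the replicate number as a block (3291) and without both Control 1 and TAF15 OE 1 (2214). Without a filter 1568 genes were lower; the cause was not tested. A limit of 1 on the absolute log2 fold change left 557 calls, 534 higher and 23 lower, with adjusted p, and 757, 714 higher and 43 lower, with unadjusted p, which follows from the limit. On FPKM with a pseudocount of 1, 1551 genes were called, 449 of them lower; with 0.1, 1630 and 473; and without a filter 669, 496 higher and 173 lower; the cause was not tested. Scaling on presynaptic genes gave 4447 calls, 4237 higher and 210 lower, since it moves every fold change up by about the fall of those genes. With 1 library left out, between 1331 and 2501 genes were called, 877 to 1293 higher and 365 to 1208 lower; the cause was not tested. Of the 34 called lists, 28 to 32 kept their call with 1 library left out, and 16 did by fry, which called 17. Under scaling on presynaptic genes 30 kept it. With an estimated correlation camera called 0, with 7 lists at an unadjusted p below 0.05. The estimate rests on the spread between 3 mice per group. A larger correlation does not by itself account for the loss. The oligodendrocyte precursor list had an estimate of -0.017, below the preset 0.01, yet its adjusted p by camera went from 0.00410 to 0.294. The p53 response list had an estimate of 0.013 and went from 7.59e-05 to 0.243. What else ended the calls was not tested. With 1 library left out, 23 to 64 of the named genes lost their call in the same direction, and 34 did without both Control 1 and TAF15 OE 1. With DESeq2 7 did, with limma-voom 14, with the size factors of DESeq2 5, with total counts 13 and with scaling on presynaptic genes 39. On FPKM 56 did with a pseudocount of 1, 47 with 0.1 and 118 without a filter. Some signs turned; the cause was not tested. Ewsr1 turned without a filter (-0.0050), with DESeq2 (-0.0057), without Control 1 (-0.018), without TAF15 OE 3 (-0.019) and without both Control 1 and TAF15 OE 1 (-0.025), and lay between -0.019 and 0.071 with 1 library left out. Fos turned without Control 2 (-0.16) and without TAF15 OE 3 (-0.19) and reached 0.19 without Control 1. Spock1 (0.027) turned under scaling on presynaptic genes, and the type I interferon list, called higher at a median of 0.50, turned to lower without both Control 1 and TAF15 OE 1 (median 0.047, adjusted p = 0.854). The dentate granule median turned without Control 1 (0.0010), with the list test still lower. With the replicate number as a block 3291 genes were called, 1904 higher and 1387 lower, and 35 lists. Of the named genes 7 lost their call, among them Igha, C3, Gbp5, H2-DMb1, Klf2 and Drd1, and 11 gained it, among them H2-DMa, H2-Oa and Arc (adjusted p = 0.00204). The deviations of libraries that share a number correlated across genes at 0.126, 0.0776 and 0.0871, and those of libraries with different numbers at -0.0950 to 0.0404. Each value for a shared number thus lay above each of the others. They were not all above the limit of 0.1 and the labels name no pairing, so the numbers were not taken to pair mice. A pairing or a batch shared by number is not excluded. In simulated data 40.3% of genes with an absolute log2 fold change of 0.5 were recovered, so small changes can be missed; depth, the number of mice and their spread were not varied apart.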

Other observations

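The scaling on presynaptic genes and the tests of the other immediate early genes, of the immunoglobulin segments and of the haemoglobin transcripts were chosen only after the result was seen. Antibody transcripts differed in class between mice, and the genes named here were chosen after their values were seen. Jchain, which links antibody units into polymers, stood at 27.9, 3.18 and 5.0 CPM in Control 1, 2 and 3 and 62.4, 84.6 and 156 in TAF15 OE 1, 2 and 3 (log2 fold change 3.07, adjusted p = 0.132). The constant gene Ighm of immunoglobulin M stood at 42.0, 16.4 and 26.4 CPM in Control 1, 2 and 3 and 75.5, 127 and 111 in TAF15 OE 1, 2 and 3 (log2 fold change 1.89, adjusted p = 0.0568). The kappa light chain gene Igkc stood at 145, 10.5 and 16.5 CPM in Control 1, 2 and 3 and 143, 256 and 634 in TAF15 OE 1, 2 and 3 (log2 fold change 2.58, adjusted p = 0.298). The immunoglobulin G genes were unlike within each group: Ighg2b stood at 68.5, 4.31 and 1.07 CPM in Control 1, 2 and 3 and 1.28, 86.9 and 149 in TAF15 OE 1, 2 and 3 (log2 fold change 1.69, adjusted p = 0.648). These 4 genes did not pass the test, and their near-identical relatives make the counts uncertain.

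Some of the lower genes were lower relative to the presynaptic genes too. With the libraries scaled on the 35 presynaptic genes, 210 of the 997 genes were still called lower. Among them were the sodium channel subunit gene Scn4b (-1.25), Slc26a10 (-1.26), the transcription factor gene Pou3f1 (-0.64), the diacylglycerol kinase gene Dgkz (-0.54), the calcium sensor gene Hpca (-0.63), the kinase gene Camk2b (-0.47), the AMPA receptor gene Gria1 (-0.39) and the cholecystokinin gene Cck (-0.38). Dgkz and Hpca were chosen after their values were seen. The 210 also held Syt7 (-0.35) and Slc17a7 (-0.27), which belong to the 35 scaling genes themselves. The median of those 35 genes stayed at -0.059 under the scaling. The CA1 and CA3 pyramidal neuron lists had medians of -0.061 and 0.027 under that scaling, and no list was tested among the 210. The scaling moved the median over all tested genes to 0.23.

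A smaller neuronal share of the RNA is a candidate explanation for the lower genes. With every other cell type unaltered it would raise their markers alike, but microglia markers had a median log2 fold change of 1.18 (SD 0.34) and astrocyte markers of 0.37 (SD 0.31), a difference of 0.81, which argues against that form of it as the whole cause; this test was chosen after the values were seen. A smaller share together with changes in glia stays open for the lower genes. That 21.1% of the 997 were still called lower under scaling on presynaptic genes does not decide it, since the scaling moved the median of the genes called lower by 0.202 and that of all tested genes by 0.201, and 18 of the 35 scaling genes were themselves called lower. For Npas4 that scaling left a log2 fold change of -1.46 (SE 0.33, adjusted p = 0.0175). The fall of Npas4 was thus larger than that of the presynaptic genes, which argues against a smaller share of neurons as a whole as its only cause. The presynaptic genes do not track single kinds of neuron, so a smaller share of only some neurons stays open. The other 31 immediate early genes had a median of -0.086 (SD 0.57) and 18 of them were below 0, which argues against a fall shared by the whole list in this tissue. Cells other than neurons also switch on genes of this list. A fall of immediate early genes within neurons therefore stays open. An effect of TAF15 on Npas4, a different recent activity of the mice and a response to the vector itself stay open and were not tested.

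The disease-associated microglia genes were higher together with the microglia markers, and more microglia of an unaltered kind are a candidate explanation. After scaling on the 26 microglia markers 9 of the 24 disease-associated genes were still called higher, among them Itgax (2.58, SE 0.28), Clec7a (2.51, SE 0.29) and Cst7 (2.32, SE 0.29), and 4 were lower, Fth1, Lpl, Timp2 and Ctsb. That scaling moves every fold change down by about the rise of the markers, so the 4 lower calls do not show a fall. Adjustment over all genes changed little in that fit, so the 9 higher calls are close to unadjusted ones. The rises of Itgax, Clec7a and Cst7 above the markers were many times their SE. For these genes this argues against a larger number of unaltered microglia as the whole cause. Smaller rises among the 9, such as that of Gpnmb (0.52, SE 0.24), are less certain. A change of state in microglia and myeloid cells that entered from blood both stay open. So does a response to injection or vector dose, since doses and the promoter of the control vector were not given in the sources used here.

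Immunoglobulin transcripts were present in all 6 libraries, with 6022, 724 and 948 counts over constant genes and Jchain in Control 1, 2 and 3 and 8787, 14838 and 35437 in TAF15 OE 1, 2 and 3, and carry-over of 1 source between libraries is a technical candidate. The 4 libraries with at least 100 heavy-chain variable counts had 4 different leading segments, Ighv3-6 in Control 1 (20.5%, interval 17.6 to 23.7%), Ighv14-3 in TAF15 OE 1 (65.1%, interval 61.4 to 68.8%), Ighv1-26 in TAF15 OE 2 (40.7%, interval 38.4 to 43.0%) and Ighv1-81 in TAF15 OE 3 (32.3%, interval 31.0 to 33.7%), which argues against it. Control 2 and 3 had 31 and 89 such counts and led with Ighv1-53 (12.9%, interval 3.63 to 29.8%) and Ighv1-64 (49.4%, interval 38.7 to 60.2%). The shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Blood left in the tissue stays open: the summed level of the haemoglobin genes Hba-a1 and Hbb-bs was 9.78, 2.72 and 0.933 CPM in Control 1, 2 and 3 and 4.86, 3.88 and 5.46 in TAF15 OE 1, 2 and 3, so the lowest of the 4 libraries was 1.43 times the higher of Control 2 and 3, but Control 1 had the highest haemoglobin and the fewest constant and Jchain counts of the 4. Antibody-secreting cells in the tissue, its borders or the meninges are another candidate that was not tested.

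The 6 libraries can be parted into 3 and 3 in 10 ways, which are too few for a share under 0.05. In 1 of the 10, the real split, edgeR called 2559 genes, 1562 higher and 997 lower. The highest count in any other split was 0 in total and in each direction, with 201 to 837 genes at an unadjusted p below 0.05; DESeq2 and limma-voom were not run on the other splits. In 1 of the 10, again the real split, 34 lists were called, and the highest number in another split was 26. The other splits gave 10 to 26 lists. Each of these splits still had more mice of 1 group on 1 side than on the other. Part of the group difference thus remained in them, and the lists called there are not a count of false calls. The mixing also put the group difference into the spread within each side, which lowers the number of genes called. The other splits therefore do not show what chance alone would give.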
